A study of Mus musculus with 10 samples.

How the data were processed

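RNA of mouse ES cells was profiled on 10 two-colour Agilent arrays, which started from 200 ng of total RNA per labelling, per the labels. The series asked how the loss of Tet1, Tet2 or both changes expression against WT cells, with lines of the same sex compared. The groups were 2 male and 2 female pairs of DKO and WT lines (6 arrays), 1 pair of T2KO 16 and T1KO 65 (2 arrays) and T1KO 99 (2 arrays). The replicate was the pair of lines or, for channels, the line, and repeat arrays of the same lines were averaged before any fit. The Cy5 channel of the T1KO 99 arrays held a sample that the labels exclude for a wrong genotype, and it entered no comparison. The normalization described below still used that channel. The T1KO 99 levels and the choice of each gene's brightest probe therefore depend on it in part. The labels place all lines on a mixed C57BL/6 background.

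The deposited scanner files hold, per the file headers, the mean intensity of each spot and the median intensity of its local background in each channel, as read by Agilent Feature Extraction 10.1.1.1 and not normalized. They also hold processed intensities that the software had corrected for background and normalized between the dyes by a linear and a lowess step, with spatial and multiplicative detrending and a surrogate value for low spots, per the file headers, and the log10 ratio of processed Cy5 to Cy3 intensity, deposited as that software wrote it. The authors' value table has 31595 probes, 31539 of which matched a probe of the scanner files, and is on a scale near log2 of Cy5 over Cy3. This was found by setting each of its columns against the log10 ratios of the same array over probes with a mean level above 9 on the log2 scale (r = 0.925 to 0.971, slope 2.77 to 2.94). The medians of its columns were 0.00178, 0.00341, 0.00544, 0.00499, 0.00321, 0.00752, 0.00669, 0.00565, 0.00212 and 0.00685. Its direction was that of Cy5 over Cy3, while its normalization and centring are not given in the sources used here. It served as an alternative.

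From the mean and background intensities, background was corrected with normexp at an offset of 50, ratios were normalized within each array by loess, and channels between arrays by Aquantile. This was done in limma 3.58.1 on R 4.3.3, with jsonlite 2.0.0 and the package data.table (version 1.17.8), and the plots were drawn with matplotlib 3.10.9. Control spots had no weight in loess and were left out afterwards, as were spots that the scanner software marked as outliers (173 to 337 per array). Normexp was fitted without the 71 to 122 gene spots per array that lay below their local background. This departs from the planned fit on all spots and was adopted after gene values had been seen, Tet1 and Tet2 among them. With all spots, the T2KO over T1KO log2 ratios were 1.31 for Tet1 and -0.49 for Tet2, against 2.04 and -1.75 in the scanner software's log ratios, and with those spots left out they were 1.99 and -1.69. The choice changed the number of genes past the threshold in DKO over WT from 363 to 947, and the planned fit is given as an alternative. Spots of a probe were averaged. Of 39429 probes, 26581 were named through a RefSeq accession and the others kept the name in the files. A probe was tested if it was well above background on all arrays of at least 1 group of genotype and sex in its channel (25865 probes). Each gene was represented by its brightest probe, which gave 20663 genes. 4302 genes had more than 1 such probe, and the text says where the other probes of a named gene disagree. The chromosome of each named gene's tested probe was compared with that of the gene in a RefSeq table of GRCm38, and the text says where they differed. Positions are those of the array's design on mm9, and no annotation of exons was used.

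DKO over WT was tested with limma (lmFit and eBayes, two-sided, Benjamini-Hochberg over genes at 0.05) on the log2 ratios of the 4 pairs against 0. The difference between male and female pairs, T2KO over T1KO, and the effect of Tet1 loss with the dye cancelled, which is the male DKO/WT mean minus the T2KO/T1KO ratio, divided by 2, came from a fit with a mean per group. T1KO and T2KO were compared with male WT on per-channel log2 intensities of single lines. In these fits the female WT lines, and for T2KO also the T1KO lines, entered only for the estimate of spread. DKO and WT were compared within arrays, which pairs the lines by hybridisation. Deviations of the DKO and WT line of a pair from the mean of their genotype over both sexes correlated at 0.301, 0.368, 0.189 and 0.512 across genes. Differences between the sexes or their slides that both channels share can add to these values. The p-values measure the spread between pairs of lines, or between lines, and no dye was swapped. The number of arrays and lines limits the precision. The male DKO, female DKO and the other arrays each lay on 1 of 3 slides.

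The 22 gene lists were the Tet and DNA methylation machinery, pluripotency, primed epiblast, trophectoderm, primitive endoderm, mesoderm and primitive streak, neuroectoderm, Nodal and Lefty signalling, imprinted, germline and 2-cell-like genes, feeder fibroblast markers, Hox genes, sex-linked genes, X-linked genes reported to escape or to dose with X number, interferon response, unfolded protein and amino acid stress, heat shock, p53 targets, glycolysis and hypoxia, cell cycle, and Polycomb and trithorax. They were tested with camera at a preset correlation of 0.01, and again with the correlation estimated per list, adjusted over the 21 lists with at least 5 measured genes. The groups, tests, lists, the alternatives not marked as added and the rule for named genes were fixed before the data were examined, and the background fit described above departs from that plan. The rule names Tet1, Tet2 and Tet3 everywhere, then the 12 largest rises and falls of DKO over WT among genes past the threshold with a symbol and the same sign in all 4 pairs. In the other comparisons it names up to 8 rises and falls past the threshold, and where fewer than 5 pass, the 5 smallest p-values as values. Of each list it names up to 4 members past the threshold, or else up to 2 with the smallest p as values, and it names sex-linked genes as a check of the labels. A few genes that the rule takes are not reported here. Other list members named in the text were chosen after their values were seen.

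The scripts were tested on simulated data with the mean levels of 20578 real genes. Each gene's variance was drawn from the prior that limma estimated on the real arrays, and the noise was independent between genes and between lines. Of the genes, 100 were changed by 1 and 100 by 2 on the log2 scale. Recovered at these sizes were 77 and 100 in DKO over WT (10 false calls), 0 and 0 in male minus female and in T2KO over T1KO (0 false calls each), 45 and 86 for Tet1 loss with the dye cancelled (7), 41 and 90 in T1KO (7) and 16 and 80 in T2KO minus male WT (5). A germline list shifted by 0.5 was called by camera and 0 of the other lists were. The real arrays may give lower recovery and more calls of lists. In the real data Tet1, the gene lost, did not pass in T1KO minus male WT (limma adjusted p = 0.181) or for Tet1 loss with the dye cancelled. The correlation estimated within a list reached 0.816 in DKO over WT.

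The alternatives were the scanner software's log ratios, median centring, quantile normalization or processed signals scaled to the 75th percentile, no background subtraction, no filter on dim probes, the mean of a gene's probes, an intensity trend in eBayes, the value table, every array with the pair as a random block, other sets of lines, channels compared without pairing, each sex alone, sex as a covariate, fry, and each pair or line left out. Added after the data were seen were normexp on all spots (the planned fit that was replaced), only genes well above background in both genotypes, DKO over WT without the first array of DKO 59 and WT 94, the gene lists with sex as a covariate, and the X-linked list without the gene whose probe the array's design places off the X.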

Results

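Gene expression was measured on 10 two-colour oligonucleotide arrays in mouse embryonic stem (ES) cells, the self-renewing cells derived from the inner cell mass of the blastocyst. The lines lacked Tet1 (T1KO), Tet2 (T2KO) or both (DKO), or were wild type (WT). Tet1, Tet2 and Tet3 encode dioxygenases that oxidise 5-methylcytosine in DNA to 5-hydroxymethylcytosine. The cells grew with LIF on irradiated feeder fibroblasts, which were removed by preplating before RNA was taken. In all, 11 labelled lines were measured: 4 WT lines (6 and 92 male, 7 and 94 female), 4 DKO lines (51 and 61 male, 60 and 59 female), 2 male T1KO lines (99 and 65) and 1 male T2KO line (16). Each DKO line was hybridised against a WT line of its own sex, with the DKO RNA in Cy5 and the WT RNA in Cy3, on 6 arrays that make 4 pairs of lines. A further 2 arrays held T2KO 16 in Cy5 against T1KO 65 in Cy3, and 2 held T1KO 99 in Cy3 against a sample that the submitters left out of their comparisons because its genotype was wrong. The replicate was the pair of lines, or the line. No array had its dyes swapped, so genotype and dye lay together in every comparison of Cy5 with Cy3.

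Each array carried 43020 spots for genes, of which 55.2% to 61.5% were well above background in Cy3 and 62.6% to 69.0% in Cy5. None of these spots was saturated. Repeat arrays of the same lines correlated at r = 0.922 to 0.971 across genes in their log ratios, whereas different DKO/WT pairs correlated at r = 0.195 to 0.476. Genes are not independent replicates, so these values describe the arrays only. The number of lines limits the precision throughout.

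The targeted genes were examined first. The tested Tet1 probe lies on chromosome 10 from 62274448 to 62274507 in mm9, the build of the array's design. In the DKO lines Tet1 fell to a log2 ratio of -2.11 (SE 0.0752, 4 pairs, limma adjusted p = 0.00708), a 4.31-fold fall that was seen in 4 of 4 pairs. Its normalized level was 12.78 to 13.13 in the WT lines and 10.52 to 11.08 in the DKO lines, and it was 11.00 in T1KO 99, 10.92 in T1KO 65 and 12.91 in T2KO 16. The other Tet1 probes had log2 ratios of -1.43 and -1.97 in DKO over WT. Tet2, probed on chromosome 3 from 133126751 to 133126810, fell by 2.10 on the log2 scale in the DKO lines (SE 0.187, limma adjusted p = 0.0213), a 4.28-fold fall. Its level was 11.51 to 12.05 in the WT lines and 9.40 to 10.11 in the DKO lines, and it was 11.57 in T1KO 99, 11.43 in T1KO 65 and 9.74 in T2KO 16. Another Tet2 probe, from 133126905 to 133126964, had a DKO over WT ratio of -1.92, whereas the one from 133176421 to 133176479 had 0.18. The labels do not say which part of either gene was deleted, so whether a probe lies inside the deletion is unknown. Tet3, probed on chromosome 6 from 83319720 to 83319779, had a DKO over WT ratio of 0.05 (SE 0.0657, limma adjusted p = 0.664) and levels between 8.35 and 8.73 in all 11 lines. Every line thus had low values of the gene or genes its label names as knocked out.

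**Figure D1:**
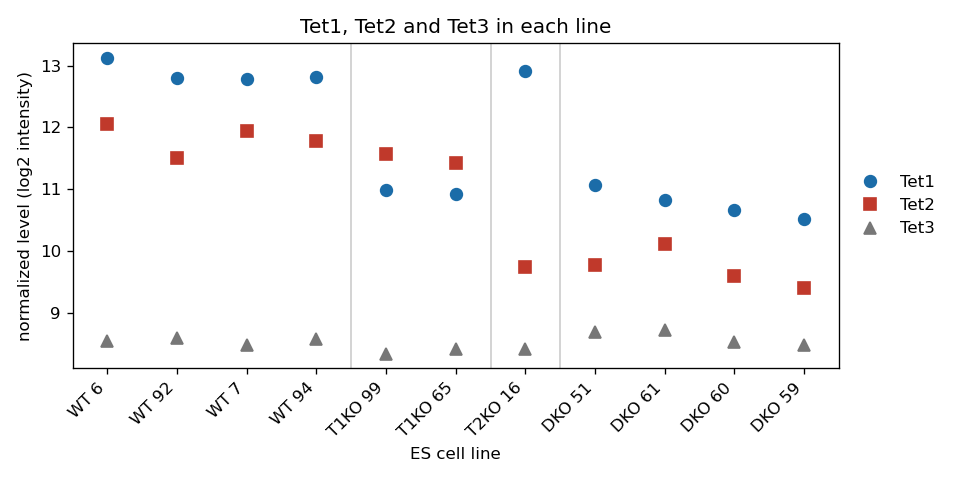
Normalized log2 intensity of Tet1, Tet2 and Tet3 (vertical axis) in each of the 11 ES lines (horizontal axis), 1 point per line and gene, with repeat arrays averaged. Tet1 lies between 10.52 and 11.08 in the T1KO and DKO lines and between 12.78 and 13.13 in the others, Tet2 between 9.40 and 10.11 in the T2KO and DKO lines and between 11.43 and 12.05 in the others, and Tet3 between 8.35 and 8.73 in all.

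The comparison of DKO with WT asked which genes change when both enzymes are lost. The gene with the largest rise was Tesc, which encodes the calcium-binding protein tescalcin, at a log2 ratio of 2.67 (SE 0.236, a 6.38-fold rise, limma adjusted p = 0.0213). Sall2, a zinc-finger transcription factor, rose by 1.51 (SE 0.126, adjusted p = 0.0213), and Dazl, a germ-cell RNA-binding protein, rose by 1.27 (SE 0.137, adjusted p = 0.0217). The gene with the largest fall was Pnp2, a purine nucleoside phosphorylase, with a log2 ratio of -3.80 (SE 0.225, a 13.9-fold fall, adjusted p = 0.0213), well above background on 5 of 6 DKO arrays. Ankrd37, a gene known to respond to hypoxia, fell to -2.65 (SE 0.27, adjusted p = 0.0217), and Hesx1, a homeobox gene of the early forebrain and pituitary, fell to -1.45 (SE 0.183, adjusted p = 0.0273).

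Among the other largest rises, Xlr4b, an X-linked gene of a family of near-identical copies that the probe may not tell apart, reached a log2 ratio of 2.41 (SE 0.385) and was well above background on 3 of 6 WT arrays. Osta, a subunit of a bile acid transporter, rose by 1.55, and Fmr1nb by 1.28. A further 6 were not well above background on any WT array, so that only a bound can be given. The desmosomal cadherin Dsc3 was at least 2.25-fold higher, the sulfotransferase Sult1d1 at least 2.42-fold, the keratin Krt78 at least 2.42-fold, the receptor Gpr35 at least 2.20-fold, Lgi3 at least 2.07-fold and Ppp1r3a, a glycogen-targeting subunit of protein phosphatase 1, at least 1.86-fold. Such bounds were set per channel after loess and Aquantile normalization, and are open to dye bias because there were no balanced swaps. Dsc3, Sult1d1, Krt78 and Gpr35 had other probes with ratios of -0.20 to 0.04, which were not well above background. Among the other largest falls, Haus4, a subunit of the augmin complex of the spindle, reached -1.64, Celsr3, a planar polarity cadherin, -1.27, Upk3bl -1.25, Krtdap -1.19, Ldhb, a subunit of lactate dehydrogenase, -1.18, As3mt, an arsenic methyltransferase, -1.13, and Sox11, a transcription factor of neural progenitors, -1.02. Adjusted p-values of these 16 genes lay between 0.00708 and 0.05, and all 24 had the same sign in 4 of 4 pairs. Of the 24, Pnp2, Hesx1, Haus4, Sall2 and Lgi3 have their tested probes on chromosome 14. The probes of Tet1 and Tet2 lie on chromosomes 10 and 3. Whether the mixed background of the lines plays a part in these changes was not tested.

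**Figure D2:**
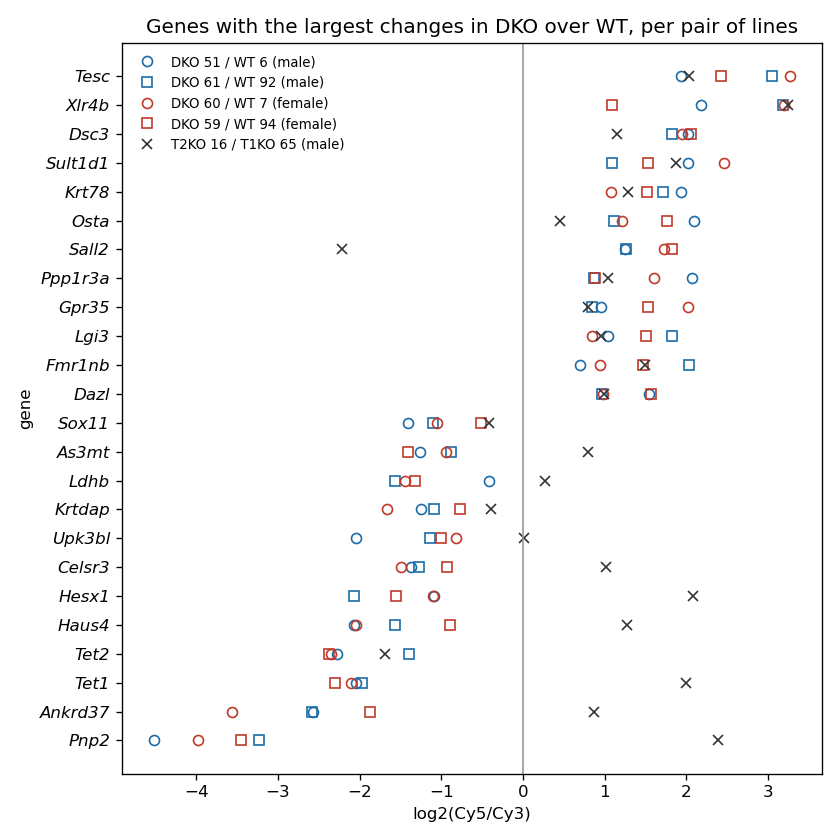
Log2 ratio of Cy5 to Cy3 (horizontal axis) of the genes with the largest changes in DKO over WT (vertical axis), with 1 open symbol for each of the 4 DKO/WT pairs of lines and a cross for T2KO 16 over T1KO 65. All open symbols of a gene lie on the same side of 0; the cross of Sall2 lies at -2.21, opposite to its DKO/WT pairs, and that of Tesc at 2.03, on the same side.

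In all, 594 genes rose and 353 fell among the 20663 tested (limma, Benjamini-Hochberg adjusted p under 0.05), and 941 of the 947 had the same sign in the 4 pairs. The median absolute log2 ratio of the 947 was 0.525. Of the rises, 63 were over 1 on the log2 scale, and 14 falls were under -1. Background correction as first planned, fitted on all spots, gave 363 genes (203 rises, 160 falls), 361 of them among the 947. The fit used here, which leaves out spots below their local background, was adopted after gene values had been seen. Under the planned fit 22 of the 41 genes that the naming rule took for passing in DKO over WT no longer passed and all kept their direction, while Tet1, Tet2, Tesc, Sall2, Dazl, Pnp2, Ankrd37 and Hesx1 passed in both. The number of calls depended on other choices too: with any pair of lines left out, with sex as a covariate, or with a variance prior that follows intensity, no gene passed limma's threshold, while 3621 to 5499 genes had an unadjusted p under 0.05, against 5422 of all pairs and about 1033 by chance. With the scanner software's own log ratios 521 genes rose and 167 fell (75.7% rises against 62.7%), and 476 of these were among the 947. With median centring 6935 rose and 590 fell (92.2%). Keeping every array, with the pair of lines as a random block, gave 761 rises and 701 falls (52.1%).

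Of the 594 rises, 182 were genes not well above background in any WT group. These had a median log2 ratio of 0.72 in DKO over WT and of 0.56 in T2KO over T1KO, which carries the dyes the same way. The 412 other rises had a median of 0.52 in DKO over WT and of 0.22 in T2KO over T1KO.

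As a list, germline genes had higher values in the DKO lines, all in Cy5, than in the WT lines, all in Cy3. Of 41 measured, 2 rose, 0 fell and 39 did not pass over all genes, 14 rose when adjusted over the list alone, and 35 had a positive ratio, with a median of 0.28 (camera adjusted p = 0.000929; adjusted p = 0.355 with an estimated correlation). The 2 were Dazl and Mov10l1, a helicase of the piRNA pathway, which rose by 0.66. Xlr4a at 2.15, Mael at 1.29 and Ddx4 at 0.57 were among the 14. The list's median was 0.24 to 0.35 in each of the 4 pairs. It was 0.66 in T2KO over T1KO, again Cy5 over Cy3, and -0.06 in T1KO minus male WT, both in Cy3. Dye and genotype cannot be told apart for this list. Relative to each gene's mean, the median of DKO 61 was -0.08, below -0.04 in WT 7 and -0.01 in WT 94. The other DKO lines lay above every WT line. X-linked genes reported to escape inactivation or to follow the number of X chromosomes were the other list past camera's threshold. Of 17, 0 passed on their own over all genes by limma's test or when adjusted over the list alone, but all 17 had a positive ratio, with a median of 0.35 (camera adjusted p = 0.0101; adjusted p = 0.99 with an estimated correlation). Their median was 0.88 in the pair DKO 60 and WT 7, against 0.02 to 0.34 in the other pairs, and the list's adjusted p was 0.184 without that pair. The array's design places the probes of 16 of the 17 on the X, and with those alone the list's camera adjusted p was 0.0223. The probe of Pgk1, at a log2 ratio of 0.53, is placed on chromosome 3.

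Genes of the methylation machinery and of chromatin included several single changes. In the Tet and DNA methylation machinery list 3 of 23 genes fell, namely Tet1, Tet2 and Uhrf1, the partner of the maintenance methyltransferase, at -0.40 (SE 0.0537, adjusted p = 0.0295; its other probe at -0.11). When adjusted over the list alone 5 fell and 2 rose, and the list's median was -0.14 (camera adjusted p = 0.0841; adjusted p = 0.801 with an estimated correlation). That list was not tested without Tet1 and Tet2, the targeted genes. In the Polycomb and trithorax list 3 of 22 rose and 1 fell (4 and 1 adjusted over the list alone, median 0.09, camera adjusted p = 0.632). Among them Cbx2 rose by 0.73 and Kdm2b by 0.39, both components of Polycomb repressive complex 1, and Sin3a, a corepressor scaffold, fell to -0.46. In the cell cycle list 2 of 27 fell, Pcna, the sliding clamp of DNA replication, at -0.52 and Ccne1, cyclin E1, at -0.41 (4 fell adjusted over the list alone, median -0.09, camera adjusted p = 0.0841). With median centring, which moved the median of all genes by 0.20, Uhrf1, Pcna and Ccne1 stood at 0.16, 0.13 and 0.15, or -0.06, -0.08 and -0.07 relative to that median.

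No list of markers of pluripotency or of the germ layers passed camera's threshold in DKO over WT, which asks for a common direction. Fry's mixed test counts changes in either direction and does not compare a list with other genes. It gave adjusted p = 0.000395 for pluripotency, 0.00338 for neuroectoderm, 0.0436 for trophectoderm and 0.0194 for imprinted genes. For the other lists of this paragraph fry's mixed adjusted p was 0.17 to 0.498. Of 26 pluripotency genes 0 passed limma's test over all genes or adjusted over the list alone (median -0.05, camera adjusted p = 0.604), with Socs3 at -0.36 and Prdm14 at 0.36. Of 24 trophectoderm genes 1 rose (2 adjusted over the list alone, median -0.03, mean 0.03, camera adjusted p = 0.984), the T-box factor Eomes at 0.89 (SE 0.153, adjusted p = 0.0463). It was also the 1 of 18 mesoderm and primitive streak genes to rise (1 adjusted over the list alone, median -0.01, camera adjusted p = 0.974). In neuroectoderm 1 of 19 rose and 2 fell (likewise 1 and 2 adjusted over the list alone, median -0.03, camera adjusted p = 0.632): Neurog2, a proneural factor, was at least 1.40-fold higher, and Sox11 and Tubb3, a neuronal tubulin at -0.62, fell. Primed epiblast (14 genes, median 0.24, camera adjusted p = 0.289), primitive endoderm (21, 0.14, adjusted p = 0.876), Nodal and Lefty signalling (12, 0.16, adjusted p = 0.289), imprinted genes (46, median 0.02, mean -0.03, adjusted p = 0.9) and Hox genes (19, 0.07, adjusted p = 0.876) had 0 members past limma's test, over all genes or adjusted over the list alone. The primed epiblast median was 1.01 in the pair DKO 60 and WT 7 and -0.37 to 0.26 in the other pairs, and that of primitive endoderm -0.39 in the pair DKO 61 and WT 92 and 0.14 to 0.29 in the others. The smallest p of these lists belonged to the imprinted gene Nnat, at -0.99 with a limma adjusted p of 0.052.

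Of the lists for stress, metabolism and other cells none passed camera's threshold. Of 34 feeder fibroblast markers 1 fell, S100a6 at -0.66 (also 1 adjusted over the list alone, median 0.04, camera adjusted p = 0.974). Their median was 0.80 in the pair DKO 60 and WT 7 and -0.45 to 0.00 in the other pairs. Of 20 genes of the 2-cell-like state 1 rose, Sp110 at 0.66, whose other probes stood at -0.19 and -0.33 (1 adjusted over the list alone, median 0.06, camera adjusted p = 0.974). The list's median was -1.08 in the pair DKO 60 and WT 7 and 0.14 to 0.60 in the other pairs. Of 24 interferon response genes 1 rose (1 adjusted over the list alone, median 0.04, camera adjusted p = 0.974), with a list median of 0.64 in the pair DKO 60 and WT 7 and -0.27 to -0.01 in the other pairs. In heat shock 1 of 12 rose, the mitochondrial chaperonin Hspd1 at 0.60 (3 rose and 1 fell adjusted over the list alone, median 0.10, camera adjusted p = 0.803). In glycolysis and hypoxia 1 of 26 rose and 1 fell (4 and 2 adjusted over the list alone, median 0.00, camera adjusted p = 0.974). The fall was that of Ankrd37, and the rise, 0.33, that of a probe named for Gapdh but placed on chromosome 8 by the array's design. The 7 other Gapdh probes, 6 of them on chromosome 6, stood between -0.27 and 0.25. The unfolded protein and amino acid stress list (19 genes, median 0.05, camera adjusted p = 0.974) and the p53 targets (20, 0.12, adjusted p = 0.302) had 0 past limma's test over all genes or adjusted over the list alone. Only 4 sex-linked genes were measured, too few for camera: 1 rose (2 adjusted over the list alone, median 0.35), the one named Ube1y1, at 0.58. Its tested probe, placed on the Y by the array's design, stood at 10.73 and 10.61 in the female and at 10.68 and 10.49 in the male WT lines, so that its signal did not follow the labelled sex. The other Ube1y1 probe stood at 6.08 and 6.28 in the female and 7.52 and 8.13 in the male WT lines, with a DKO over WT ratio of -0.02.

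The design compared lines of the same sex, so the DKO effect was set against itself in males and females, with 2 pairs each. The sexes lay on different slides and cannot be told apart from them. No single gene differed by limma's test (smallest adjusted p = 0.297; 1061 genes with an unadjusted p under 0.05, about 1033 by chance). Gm10499 had the smallest p, but it was not well above background on any female array, with levels of 6.21 to 6.45, so its DKO effect was measured in males only, at -3.58. A_55_P2145237 at 1.86, Glrx2 at -1.30, Gad1, which makes GABA, at 1.49 and Cdh1, encoding E-cadherin, at 3.16 had adjusted p = 0.828. The differences were 0.19 for Tet1, 0.53 for Tet2 and 0.15 for Tet3. By camera, the feeder fibroblast markers had the smallest p of the lists, with a median of -0.66 and a negative value in 33 of 34 genes (camera adjusted p = 2.64e-11; adjusted p = 0.492 with an estimated correlation). Interferon response (-0.45), primed epiblast (-0.69), primitive endoderm (-0.27), imprinted (-0.26) and X-linked genes (-0.30) also had lower, and 2-cell-like genes (0.58) and p53 targets (0.23) higher, values in males, with camera adjusted p between 1.61e-05 and 0.00319. With an estimated correlation none of these 8 held (adjusted p = 0.492 to 0.588). Adjusted over the list alone, 1 of the feeder markers passed and 0 of the others by limma's test. Without the pair DKO 51 and WT 6, without DKO 61 and WT 92 or without DKO 60 and WT 7, 6, 5 and 5 of the 8 lists passed camera's threshold. The first run lost primed epiblast (camera adjusted p = 0.0851) and X-linked genes (adjusted p = 0.218). The run without DKO 61 and WT 92 lost imprinted (adjusted p = 0.347) and 2-cell-like genes (adjusted p = 0.192), and primitive endoderm turned its direction (adjusted p = 0.789). The run without DKO 60 and WT 7 lost 2-cell-like (adjusted p = 0.495) and primed epiblast genes (adjusted p = 0.106), and the X-linked list turned its direction (adjusted p = 0.439). Relative to each gene's mean, WT 7 was the extreme of the 4 WT lines in primed epiblast (-0.87), 2-cell-like (1.27), feeder (-0.49) and interferon genes (-0.44).

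For the loss of Tet1 alone, the 2 T1KO lines were compared with the 2 male WT lines across arrays, all in Cy3. The female WT lines entered this fit for the estimate of spread only. T1KO arrays lay on a slide of their own, so that slide and genotype cannot be told apart. Tet1 had the smallest p, with a difference of -2.0 (SE 0.138, limma adjusted p = 0.181), against -0.28 for Tet2 and -0.20 for Tet3. No gene passed limma's threshold, with 2821 at an unadjusted p under 0.05. The next smallest p-values, all with adjusted p = 0.181, were those of Zim3, which was at least 2.10-fold lower, Gm11559 at 2.95, NAP000142-002 at -1.26 and A_55_P2113768 at -1.25. Of the gene lists, trophectoderm was higher, with 20 of 24 differences positive and a median of 0.39 (camera adjusted p = 0.0027; adjusted p = 0.9 with an estimated correlation). Its members Eomes and Hand1 stood at 1.11 and 0.96, and 1 member rose when adjusted over the list alone. Primitive endoderm (median 0.28, 18 of 21 positive, camera adjusted p = 0.0255) and p53 targets (median 0.32, 16 of 20 positive, adjusted p = 0.0175) were also higher, with 0 members past limma's test adjusted over the list alone, and an adjusted p of 0.9 for each with an estimated correlation. Line by line, relative to each gene's mean, the primitive endoderm median was 0.10 in T1KO 99 and 0.63 in T1KO 65, against -0.28 in WT 6 and 0.29 in WT 92, so that T1KO 99 lay below WT 92. The trophectoderm median was 0.26 in both T1KO lines, -0.30 in WT 6 and 0.13 in WT 92, and that of the p53 targets was -0.03 and 0.30 in T1KO 99 and 65, -0.37 in WT 6 and -0.11 in WT 92. With all lines of both channels in the fit 44 genes passed.

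The T2KO line was compared with the 2 male WT lines in the same way, but its RNA was in Cy5 and theirs in Cy3, and the lone line was assumed to vary like the others. Dye, slide and genotype cannot be told apart here. Tet2 had a difference of -2.04 (SE 0.243, limma adjusted p = 0.143), Tet1 of -0.05 and Tet3 of -0.16. The 2 genes past limma's threshold were Gas5, a non-coding host of small nucleolar RNAs, at -3.55 (SE 0.17, adjusted p = 0.0114), and Miip at -2.66 (SE 0.123, adjusted p = 0.0114). The other Gas5 probes stood at -0.65 and 0.34. With the planned background fit on all spots neither passed (adjusted p = 0.374 for both). Both calls were also lost without WT 6, without WT 92 or with the compared lines alone, while 144 genes passed on processed signals scaled to their 75th percentile. Gm5801 at -2.10, by a probe placed on another chromosome than that gene, Gm4371, at least 3.86-fold higher, and Gja1, a connexin, at -2.10 came next (adjusted p = 0.0613, 0.0963 and 0.106). Germline genes were higher, with 34 of 41 positive and a median of 0.48 (camera adjusted p = 7.33e-07; adjusted p = 0.649 with an estimated correlation), and 7 rose when adjusted over the list alone, among them Dazl at 1.33 and Tex101 at 1.24. Primed epiblast (-1.13, camera adjusted p = 0.00396), feeder markers (-0.47, adjusted p = 0.00321) and interferon response (-0.54, adjusted p = 0.00496) had lower and 2-cell-like genes (0.47, adjusted p = 0.0313) higher medians. None of them held with an estimated correlation (adjusted p = 0.649 to 0.66). Relative to each gene's mean, the feeder median was -0.31 in T2KO 16, -0.13 in WT 6, 0.41 in WT 92 and -0.49 in the female line WT 7. The interferon median was -0.38 in T2KO 16 and -0.44 in WT 7. That of 2-cell-like genes was 0.03 in T2KO 16, 0.16 in WT 94 and 1.27 in WT 7. In these lists T2KO 16 thus lay within the range of the WT lines of both sexes. The primed epiblast median was -0.91 in T2KO 16 and -0.87 in WT 7, and the germline median of 0.32 lay above every WT line. Adjusted over the list alone, 1 primed epiblast gene fell and 0 of the feeder, interferon and 2-cell-like genes passed limma's test.

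T2KO 16 and T1KO 65 were hybridised directly to each other, 1 pair of lines that was assumed to vary like the DKO/WT pairs. Tet1 was 1.99 (SE 0.137) and Tet2 -1.69 (SE 0.325) in T2KO over T1KO, and Tet3 was 0.00. No gene passed limma's threshold (smallest adjusted p = 0.245, 2704 with an unadjusted p under 0.05). On simulated data 0 of 100 changes of 2 on the log2 scale were recovered in this comparison, and likewise in that between the sexes. With the simulated spread neither fit thus had power for single genes. The smallest p-values were those of 3830417A13Rik (-2.36), Sall2 (-2.21), Glrx2 (-2.29), LOC100503910 (-1.98, well above background on 1 of 2 T2KO arrays) and A_55_P2142668 (-1.92). By lists, the pluripotency genes were higher in T2KO, with a median of 0.38 and 20 of 26 positive (camera adjusted p = 0.00136; adjusted p = 0.492 with an estimated correlation), among them Nr5a2 at 2.04 and Prdm14 at 1.30. Germline genes were also higher, with a median of 0.66 and 35 of 41 positive (camera adjusted p = 2.1e-07), and so were 2-cell-like genes (0.52, adjusted p = 0.0113), with adjusted p = 0.442 and 0.763 with an estimated correlation. Primed epiblast genes were lower, with a median of -1.21 and 12 of 14 negative (camera adjusted p = 8.48e-05; adjusted p = 0.492 with an estimated correlation), among them Krt18, a keratin, at -3.04 and Sox3 at -2.17. Primitive endoderm (-0.69, camera adjusted p = 4.1e-06), trophectoderm (-0.41, adjusted p = 0.00342), mesoderm and primitive streak (-0.36, adjusted p = 0.00342), interferon response (-0.62, adjusted p = 5.15e-05) and p53 targets (-0.18, adjusted p = 0.0145) were lower too. With an estimated correlation none of these 5 held either (adjusted p = 0.492 for each). Adjusted over the list alone, 3 pluripotency and 8 germline genes rose and 5 primed epiblast, 5 interferon and 2 primitive endoderm genes fell. In trophectoderm 1 rose and 2 fell, and the mesoderm, 2-cell-like and p53 lists had 0 past limma's test so adjusted. The feeder markers had a median of -0.09 (camera adjusted p = 0.182).

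The effect of Tet1 loss could be estimated with the dye cancelled, as the mean of DKO minus T2KO and T1KO minus WT in males, although it rests on arrays of different slides and shares the T2KO and T1KO arrays with the direct comparison. Tet1 had a value of -2.0 (SE 0.084, limma adjusted p = 0.0823) and Sall2 of 1.74 (SE 0.0752, adjusted p = 0.0823). Gm10499 stood at -2.30 (adjusted p = 0.0823), Zfp467 at 1.44 and 3830417A13Rik at 1.23 (both adjusted p = 0.178). Tet2 was -0.07 and Tet3 0.06. No gene passed limma's threshold, with 2133 at an unadjusted p under 0.05. Pluripotency genes were lower, with 23 of 26 negative and a median of -0.22 (camera adjusted p = 0.000397; adjusted p = 0.462 with an estimated correlation), among them Zfp42 at -0.47 and Esrrb at -0.43. Germline genes were lower as well (-0.15, camera adjusted p = 0.0138; adjusted p = 0.534 with an estimated correlation). Higher were primed epiblast (0.35, adjusted p = 0.00103), primitive endoderm (0.39, adjusted p = 0.000653), trophectoderm (0.17, adjusted p = 0.0243), interferon response (0.21, adjusted p = 0.0128) and p53 targets (0.27, adjusted p = 0.000297). With an estimated correlation none of these 5 held (adjusted p = 0.462 to 0.619). In the primed epiblast list Krt18 stood at 1.56 and Sox3 at 1.29, and those 2 rose when adjusted over the list alone, as did 1 trophectoderm gene. The other 5 of these 7 lists had 0 past limma's test so adjusted. Per pair, the pluripotency median was -0.02 and -0.04 in the male DKO/WT pairs and 0.38 in T2KO over T1KO. That of primed epiblast was -0.37 and 0.26 against -1.21, and that of primitive endoderm 0.14 and -0.39 against -0.69. Those lists thus rest largely on the single T2KO and T1KO pair. For p53 targets the medians were 0.18 and 0.33 against -0.18. In T1KO minus male WT the pluripotency list did not pass (median -0.11, camera adjusted p = 0.623).

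The effects in the female DKO lines and in the T1KO lines, which share no WT line, correlated weakly across 20654 genes (Pearson r = 0.121, Spearman rho = 0.121). Single pairings of a female DKO/WT pair with a T1KO line against male WT gave r = 0.0424 to 0.206.

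The labelled sex was checked on sex-linked genes. Kdm5d was not well above background on any array, Xist was so only in DKO 60, and Uty only in DKO 61 and on 1 of 2 arrays of DKO 59. The Y-linked genes Eif2s3y and Ddx3y stood at 9.18 and 8.76 in WT 6, 9.31 and 8.43 in WT 92, 10.76 and 9.97 in T1KO 65, 10.86 and 8.65 in T2KO 16, 10.42 and 9.65 in DKO 61 and 8.74 and 7.18 in DKO 51. In the 4 female lines they lay between 6.11 and 6.92. T1KO 99, labelled male, had 6.67 and 7.30, of which Eif2s3y was not well above background on either array.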

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

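Of the tests in this part, those on the dim rises, on Gas5 and on T1KO 99 were chosen only after the results were seen.

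Turning the sign of some of the 4 pairs gives 8 distinct patterns, too few for a share under 0.05. The real pattern, 1 of the 8, had 947 genes past the threshold in DKO over WT, and the highest of the others had 1. All 4 pairs carried the dyes the same way, so turning signs cannot tell genotype from dye.

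In the fall of Tet2 the pair DKO 61 and WT 92 stood apart, with a log2 ratio of -1.39 against -2.37 to -2.28 in the other pairs. The same pair stood apart in Hoxa7, at -0.055 against -0.18 to -0.16, a gene that did not pass the threshold (limma adjusted p = 0.197). By chance about 1 group in 20 stands apart in this way, and 2 of the 59 genes looked at did.

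The DKO effect differed between the sexes in 8 lists by camera's test of the difference (adjusted p = 2.64e-11 to 0.00319). The medians of male minus female were -0.69 for primed epiblast, -0.27 for primitive endoderm, -0.26 for imprinted, 0.58 for 2-cell-like, -0.66 for feeder fibroblast, -0.30 for X-linked, -0.45 for interferon response and 0.23 for p53 target genes. With an estimated correlation none of the 8 held (adjusted p = 0.492 to 0.588), and sex and slide cannot be told apart. Without DKO 51 and WT 6 the primed epiblast and X-linked calls were lost, without DKO 61 and WT 92 the imprinted, 2-cell-like and primitive endoderm calls, and without DKO 60 and WT 7 the 2-cell-like, primed epiblast and X-linked calls. Only the feeder, interferon and p53 calls held in each of the 4 runs that left out a pair.

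The sample that the submitters left out for its wrong genotype had a Tet1 value of 2.00 and a Tet2 value of -1.57 over T1KO 99, and no genotype was assigned to it.

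The rises in DKO over WT that were not well above background in any WT group were 182 genes with a median of 0.72. Loss of Tet1 alone stays open: their median was 0.0502 in T1KO minus male WT, both in Cy3, but only 6 of the 182 were well above background in T1KO, and near the floor a change can go unseen. A dye effect of single probes may account for them, since their median was 0.56 in T2KO over T1KO, again Cy5 over Cy3. Loss of Tet2 cannot be told apart from the dye for these genes, because 0 Cy3 channels held a line without Tet2.

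The Gas5 value of -3.55 in T2KO minus male WT came from 1 of 3 probes. A lower level of the whole RNA is argued against by the other probes, the highest of which stood at 0.34. A difference in sequence or transcript under a single probe may account for it, as only 1 of the 3 probes lay at least 1 log2 unit lower. At the same probe the pair DKO 51 and WT 6 had a ratio of -2.98, and the other DKO/WT pairs, whose DKO lines lack Tet2 as well, had -0.42 to 0.55. The left-out sample, whose Tet2 value was low, had -3.61 there over T1KO 99.

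T1KO 99, labelled male, had Eif2s3y within and Ddx3y above the range of the female lines. A swap of genotype is argued against, since Tet1 in line 99 minus the lowest WT line was -1.78. A line of the other sex could not be told apart from a male line: the X-linked median of line 99 minus that of T1KO 65 was 0.00129, against 0.137 between female and male WT lines, but the 2 female WT lines themselves differed by 0.176. Loss of Y-linked expression in a male line was not tested.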

How the results depend on the processing

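Normexp on all spots, the restriction to genes well above background in both genotypes, the run without the first array of DKO 59 and WT 94, the lists with sex as a covariate and the X-linked list without its probe off the X were run only after results were seen, the first because it is the planned fit that was then replaced. The cause of the changes below was not tested, except that some settings leave fewer lines or genes. The 947 calls of DKO over WT became 363 with normexp on all spots, 7525 with median centring, 1462 with every array and the pair as a random block, 571 with the value table and 478 in genes well above background in both genotypes. They became 0 in limma with an intensity trend (5499 genes at an unadjusted p under 0.05), with sex as a covariate (5270), in males alone (2923), in females alone (3358) and, as a range, 0 to 0 when any pair was left out (3621 to 4873, smallest adjusted p 0.058 to 0.118). Compared without the pairing of the array as a block and with sex as a covariate, changed together, 820 genes passed, 638 of them among the 947, and 31 of the 41 genes taken by the naming rule passed. The scanner's log ratios (688), no filter (1152), the mean of probes (808), no background subtraction (1046) and the run without an array (879) stayed within 1.5 times. With the scanner's log ratios, however, only 476 of the 947 calls were shared. There 17 of the 41 genes taken by the naming rule no longer passed. Where a setting gave a value, these 41 genes kept their direction, except Uhrf1 at 0.16, Pcna at 0.13 and Ccne1 at 0.15 with median centring, which raised the median of all genes by 0.20. In T1KO minus male WT the 0 calls of limma (2821 unadjusted) became 4 with processed signals at the 75th percentile, 1 with all 4 WT lines and 44 with all lines in the fit. In T2KO minus male WT the 2 became 144 with processed signals, 1 with the mean of probes, 9 with a trend, 5 with all 4 WT lines, and in limma 0 with only the lines compared (2987 unadjusted), 0 with normexp on all spots (2356) and 0 to 0 with WT 6 or WT 92 left out (2466 to 2693); leaving out the lone T2KO line gives no value. With every array and the pair as a random block, the 0 of T2KO over T1KO became 550 and that of Tet1 loss with the dye cancelled 306, and the latter became 3 without a filter. Male minus female stayed at 0 in limma under all settings run (470 to 1838 unadjusted). The 2 gene lists past the threshold in DKO over WT became 0 with an estimated correlation, 9 with median centring and 2 to 5 when a pair was left out (5 without DKO 51 and WT 6, 4 without DKO 61 and WT 92). With fry's test for a common direction 2 lists passed, but not the same 2. The germline list held (fry adjusted p = 0.0285) and the X-linked list did not (fry adjusted p = 0.64). The Tet and DNA methylation machinery, which holds the targeted Tet1 and Tet2, passed instead (fry adjusted p = 0.0161). The correlation of the female DKO and T1KO effects lay between 0.101 and 0.121. Signal over background limits the rises, as 148 of the 594 were not well above background on any WT array.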

Other observations

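The values in this part were picked out after the results were seen, and no further test was run on them.

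For the X chromosome, each gene was set against its own mean over the 11 lines, and only genes with a mean level above 9 on the log2 scale were used. Relative to autosomal genes (10825), the median of 449 X-linked genes so centred was 0.542 in DKO 60, 0.278 in DKO 59, 0.124 in DKO 61 and -0.204 in DKO 51. It was 0.105 in WT 94, -0.0715 in WT 7, -0.117 in WT 6, -0.123 in WT 92, -0.182 in T1KO 99, -0.183 in T1KO 65 and -0.19 in T2KO 16.

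Miip, past the threshold in T2KO minus male WT, also fell in DKO over WT, at a log2 ratio of -0.98 (SE 0.105, limma adjusted p = 0.0217), and had -0.75 in T1KO minus male WT, which did not pass. Its level was 9.94 to 10.55 in the WT lines, 9.76 and 9.78 in T1KO 99 and 65, 8.67 to 9.86 in the DKO lines and 7.85 in T2KO 16. Cdh1 varied within genotypes, with levels of 9.10 to 12.96 in the WT lines, 8.80 and 12.48 in T1KO 99 and 65, and 10.57 to 12.36 in the DKO lines.

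In the left-out sample over T1KO 99, Cy5 over Cy3, 2-cell-like genes had a median of 1.31, germline genes of 1.21, X-linked genes of 0.76 and feeder fibroblast markers of 0.66.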
